A study of Mus musculus with 47 samples.

How the data were processed

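Total RNA was taken from the duodenum and ileum of male C57BL/6J mice aged 15 to 16 weeks, fed ad libitum, either germ-free (GF, raised without microorganisms) or conventionally raised (convR, with a gut flora). Tissue was collected at 6 zeitgeber times (ZT, hours after lights on): 2, 6, 10, 14, 18 and 22. According to the labels, stranded total-RNA libraries were made from 250 ng after removal of ribosomal RNA, with 12 cycles of PCR, pooled by 24 and read as paired ends of 100 nt. Reads were aligned with STAR 2.4.0i to the mouse genome mm10. The deposited tables hold raw counts of reads over the exons of each gene, with the summed exon length. The counting program, its annotation and its strand setting are not given in the sources used here. Counts of overlapping genes, and of near-identical copies such as the alpha-defensins, are therefore uncertain.

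The tables list 38087 genes, of which 36308 were matched to GENCODE M21 by gene identifier for symbols and coordinates, and 7968 of these carry another symbol there. Read counts were kept as deposited. Libraries were scaled by the trimmed mean of M values (TMM) within each comparison. Genes too low to test were dropped with the edgeR filter for low counts at a minimum of 10 counts, which left 17986 genes in duodenum, 18082 in ileum and 19000 in the model of both tissues. The tissue comparisons kept 18164 genes in convR and 17909 in GF. Levels are given as CPM (counts scaled to the library total) with the SD over libraries.

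The GF and convR groups were compared with edgeR 4.0.16 quasi-likelihood tests with robust dispersion, with ZT as a factor in each model. All p-values are two-sided, and adjusted p-values follow Benjamini-Hochberg over all genes of a comparison with a threshold of 5%, unless said to be adjusted over the list alone. Named gene lists of cell types and pathways, 44 in total, were fixed in advance, and each was tested against all other genes with camera of limma 3.58.1 at its preset inter-gene correlation of 0.01. A repeat with an estimated correlation, and fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, were run beside it. Rhythms were fitted as a cosine of 24 h with edgeR in each tissue and status, and the interaction with status tested their difference. Peak times and peak-to-trough ranges of the clock list come from a least-squares cosine of log2 CPM with 0.5 added. Those of other genes, and summaries over all genes rhythmic in both groups, come from the edgeR cosine. The shift of the clock was tested by exact enumeration of all swaps of GF and convR labels within each time, used in place of the resampling first planned.

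Genes named in the text were chosen by a rule written in advance. Predicted genes, pseudogenes and immunoglobulin or T-cell receptor segments were passed over, and a mean of at least 2 CPM was required. The rule takes, per tissue, the 6 largest rises and 6 largest falls between GF and convR that pass the threshold with the same sign at all 6 times. To these it adds up to 3 members of each list with the smallest p, the 8 genes with the smallest p for the tissue difference, and the 5 largest rises and 5 largest falls between ileum and duodenum in convR. For rhythms it takes the 6 smallest p in convR, the 6 smallest in GF, the 8 smallest for their difference, and the clock list.

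Comparisons, gene lists, thresholds, the naming rule and most alternatives were chosen before the data were examined. Replicate numbers do not say whether libraries come from separate animals, so p-values measure the spread between samples. Whether equal numbers mark the same mouse in duodenum and ileum was checked by correlating residuals of libraries with equal numbers and times. In convR the correlation between tissues was positive at 6 of 6 times (0.207 to 0.588). Across status, and between tissues in GF, the correlations crossed 0 (lowest -0.117 in duodenum, -0.0458 in ileum and -0.0282 in GF). Replicate numbers entered as a block only in an alternative fit, as planned. For an alternative chosen after the data were seen, libraries stood apart by a pancreas or stomach marker mean over 100 CPM, a TMM factor over 1.2, or, in ileum, Fabp6 under 1000 CPM. In duodenum these 7 were convR ZT6 replicate 1 (TMM factor 1.273), convR ZT14 replicates 1 and 2, convR ZT22 replicate 2, GF ZT6 replicate 1 and GF ZT22 replicates 1 and 2. In ileum they were convR ZT6 replicate 2 (Fabp6 at 206.6 CPM) and GF ZT22 replicate 2 (609.7 CPM). As a check, known changes were added to simulated counts before the real data were run. Of genes given a log2 change of 1, the tests recovered 95.5% in duodenum, 95.5% in ileum, 89.6% for the tissue difference, 92.5% between tissues in convR and 95.5% in GF. For a rhythm difference of that size the tests recovered 22.4% in duodenum and 56.7% in ileum. The simulation changed few genes: of 17986 in duodenum, 67 by 0.5, 67 by 1 and 66 by 2 log2. In the real data 46.3% passed there, so scaling under that many changes was not tested. Simulated rhythms were given to GF only, so the power to find a shift in peak time was not measured.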

Results

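Transcript levels were measured by RNA sequencing in 47 libraries of mouse small intestine, 24 of duodenum (the part next to the stomach) and 23 of ileum (the part next to the colon). The duodenum gave 12 convR and 12 GF libraries and the ileum 12 convR and 11 GF libraries. Each group had 2 libraries per time, except GF ileum at ZT2 with 1. Total counts per library ran from 22.5 to 41.9 M with a median of 31.9 M. The group means were 33.7 ± 5.02 M in convR duodenum, 31.6 ± 4.95 M in GF duodenum, 32.9 ± 4.19 M in convR ileum and 31.5 ± 3.94 M in GF ileum (SD over libraries). Between the 2 libraries of a time and group the differences exceeded counting noise, with a chi-square per degree of freedom of 18.4 to 159 over 23 pairs. Markers of pancreas acinar cells averaged 33.94 CPM or more in 8 duodenum libraries, 4 of them over 100 CPM, and 7.041 CPM or less in the others. Markers of stomach and Brunner glands averaged over 100 CPM in convR ZT14 replicate 1 (1469 CPM) and GF ZT22 replicate 2 (463.2 CPM).

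The first comparison asks which transcripts of the duodenum differ between GF and convR mice. Transcripts of antibody-secreting cells fell most as a group: all 15 measured B and plasma cell markers were lower in GF, with a median log2 fold change of -2.78 (camera adjusted p = 2.07e-23, adjusted p = 0.0716 with an estimated correlation). Jchain (ENSMUSG00000067149, mm10 chr5:88519809-88527891), which joins the units of polymeric IgA, fell 8.39-fold from 1528 ± 365 to 189.7 ± 75.7 CPM (SD, n = 12 and 12). Its log2 fold change was -3.07 ± 0.17 (SE, edgeR quasi-likelihood adjusted p = 9.24e-11). Igha, the constant region of the IgA heavy chain, fell by 3.06 log2, and Mzb1, a chaperone cofactor of plasma cells, fell by 3.03. Markers of lymph node and follicle, which share Cr2 with this list, averaged 8.34 ± 8.42 CPM in convR and 4.80 ± 4.13 CPM in GF.

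Defence genes of the duodenal epithelium were lower in GF. Of 16 measured antimicrobial genes, 13 fell, 1 rose and 2 did not pass, with a median log2 fold change of -1.14 (camera adjusted p = 3.29e-09, adjusted p = 0.0817 with an estimated correlation). Adjusted over the list alone, 15 passed. Reg3g (ENSMUSG00000030017, chr6:78466269-78468872), a lectin that kills Gram-positive bacteria, fell from 1099 ± 860 to 23.79 ± 15.6 CPM (SD, n = 12 and 12), a log2 fold change of -5.54 ± 0.477 (SE, adjusted p = 7.43e-08). It resembles its neighbours of the Reg3 family in sequence, so part of its count is uncertain. Duox2, an oxidase that makes hydrogen peroxide, fell by 5.31 log2 from 79.94 ± 97.9 to 1.525 ± 0.719 CPM, and its maturation factor Duoxa2 fell by 5.32. Nos2, the inducible nitric oxide synthase, fell by 6.73 ± 0.856 (SE) from 80.63 ± 199 to 0.3594 ± 0.211 CPM. Slc5a8, a carrier of short-chain fatty acids, fell by 5.55 and Mptx2, a pentraxin of Paneth cells, fell by 4.83. Of 15 Paneth cell markers, several of them also antimicrobial genes, 14 fell (median -1.37, camera adjusted p = 1.87e-09, adjusted p = 0.531 with an estimated correlation). Mmp7, which activates defensins, fell by 1.88, and Lyz1, the Paneth cell lysozyme, fell by 1.03 from 1611 ± 414 to 792.3 ± 230 CPM.

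MHC class II genes and marker transcripts of resident immune cells were lower as well. Of 11 MHC class II genes 10 fell (median -1.36, camera adjusted p = 4.02e-05, adjusted p = 0.531 with an estimated correlation), and 11 passed when adjusted over the list alone. Cd74 (ENSMUSG00000024610, chr18:60803848-60812652), the invariant chain that escorts class II molecules, fell from 734.3 ± 331 to 252 ± 60.2 CPM (SD, n = 12 and 12), a log2 fold change of -1.50 ± 0.188 (SE, adjusted p = 2.81e-06). Interferon-response genes fell in 15 of 32 cases and rose in 0 (median -0.41, camera adjusted p = 4.67e-04, adjusted p = 0.563 with an estimated correlation). They include Ubd, a ubiquitin-like protein, at -4.14, and Zbp1, a sensor of nucleic acids, at -1.89. T-cell and intraepithelial lymphocyte markers fell in 18 of 20 cases (median -0.70, camera adjusted p = 3.03e-08, adjusted p = 0.531 with an estimated correlation), among them Lck, a kinase of the T-cell receptor, at -1.07. Macrophage and dendritic cell markers fell in 11 of 15 cases and in 13 when adjusted over the list alone (median -0.50, camera adjusted p = 1.22e-04, adjusted p = 0.531 with an estimated correlation). Lyz2, the lysozyme of myeloid cells, fell by 1.22. Adjusted over the list alone, 15 interferon-response genes and 18 T-cell markers passed.

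Transcripts of dividing cells were slightly lower. Of 25 cell-cycle genes 23 fell (23 adjusted over the list alone, median -0.40, camera adjusted p = 3.18e-11, adjusted p = 0.371 with an estimated correlation). Top2a, a topoisomerase of dividing cells, fell from 241.4 ± 34.9 to 164.8 ± 20.2 CPM. Stem cell markers fell in 7 of 13 cases (7 adjusted over the list alone, median -0.27, camera adjusted p = 0.0249, adjusted p = 0.531 with an estimated correlation), with Lgr5, the receptor of crypt base stem cells, at -0.65. Genes of the unfolded protein response fell in 13 of 17 cases and rose in 2 (15 adjusted over the list alone, median -0.45, camera adjusted p = 1.37e-04, adjusted p = 0.531 with an estimated correlation), with Hsp90b1, a chaperone of the endoplasmic reticulum, at -0.67.

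Lists of nutrient handling and detoxification held more rises than falls in GF duodenum, and none of their calls held with an estimated correlation. Drug-metabolism genes rose in 15 of 26 cases and fell in 3 (19 adjusted over the list alone, median 0.41, camera adjusted p = 1.14e-04, adjusted p = 0.531 with an estimated correlation). Cyp2j6, an epoxygenase, rose from 169 ± 51.8 to 595.3 ± 83.8 CPM (SD, n = 12 and 12), a log2 fold change of 1.87 ± 0.128 (SE). The largest rise that kept its sign at all times was that of Cyp2c38 (ENSMUSG00000032808, chr19:39389556-39463075), from 1.016 ± 0.539 to 16.57 ± 5.12 CPM, 4.07 ± 0.229 log2 (SE, adjusted p = 1.66e-10). Its relative Cyp2c29 rose by 3.88, and reads shared within that gene family are uncertain. Carbohydrate genes rose in 10 of 15 cases and fell in 0 (10 adjusted over the list alone, median 0.43, camera adjusted p = 1.11e-04, adjusted p = 0.531 with an estimated correlation). Treh, the trehalose-splitting enzyme of the brush border, rose from 359.1 ± 74.2 to 687.5 ± 63.9 CPM. Fatty-acid oxidation genes rose in 11 of 23 cases (11 adjusted over the list alone, median 0.31, camera adjusted p = 0.00117, adjusted p = 0.545 with an estimated correlation), with Ppara, their receptor, at 0.87, and fell in 0. Fat-absorption genes rose in 9 of 23 cases and fell in 1 (10 adjusted over the list alone, median 0.21, camera adjusted p = 0.0177, adjusted p = 0.627 with an estimated correlation), with Cd36, a fatty-acid transporter, up from 74.89 ± 17.3 to 218.2 ± 68.4 CPM. Peptide and amino-acid uptake genes rose in 8 of 18 cases (9 adjusted over the list alone, median 0.36, camera adjusted p = 0.00852, adjusted p = 0.563 with an estimated correlation), among them Ace, a peptidase, at 1.18.

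Smaller groups in GF duodenum moved as follows. Enteroendocrine markers rose in 8 of 17 cases and fell in 2 (median 0.35, camera adjusted p = 0.013, adjusted p = 0.531 with an estimated correlation), with the hormone gene Sst at 1.16. Cholesterol-synthesis genes rose in 9 of 25 cases and fell in 1 (median 0.12, camera adjusted p = 0.0249, adjusted p = 0.563 with an estimated correlation). Markers of proximal intestine rose in 8 of 13 cases (median 0.38, camera adjusted p = 0.0134, adjusted p = 0.531 with an estimated correlation). Clock-controlled nutrient transporters rose in 8 of 12 cases and fell in 1 (median 0.46, camera adjusted p = 0.0241, adjusted p = 0.531 with an estimated correlation). The mean level of clock genes rose in 7 of 19 cases and fell in 2 (median 0.42, camera adjusted p = 0.0473, adjusted p = 0.531 with an estimated correlation). The clock list also lost its call with replicate numbers as a block. Adjusted over the list alone, 10 enteroendocrine, 10 cholesterol, 8 proximal, 10 transporter and 11 clock genes passed. Red blood cell markers rose in 5 of 5 cases (median 0.94, camera adjusted p = 0.013, adjusted p = 0.531 with an estimated correlation), from a mean of 1.98 ± 0.551 to 3.92 ± 1.36 CPM. Endothelial and fibroblast markers fell in 7 of 14 cases without a passing list (camera adjusted p = 0.0843), and MHC class I genes rose in 2 and fell in 4 of 15 (camera adjusted p = 0.755). Goblet, tuft, adipocyte, pancreas, stomach and mitochondrial lists did not pass.

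Over all genes of the duodenum, 8328 of 17986 passed with edgeR, 4041 higher and 4287 lower in GF. Of these 838 differed by at least 1 log2, 279 upward and 559 downward. Scaled by library size only, 2143 were higher and 6618 lower, as the median log2 fold change over all genes moved by -0.129. The share of higher calls therefore depends on the scaling. With library size only the stem cell list gave a camera adjusted p = 0.0503, above the threshold.

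**Figure D1:**
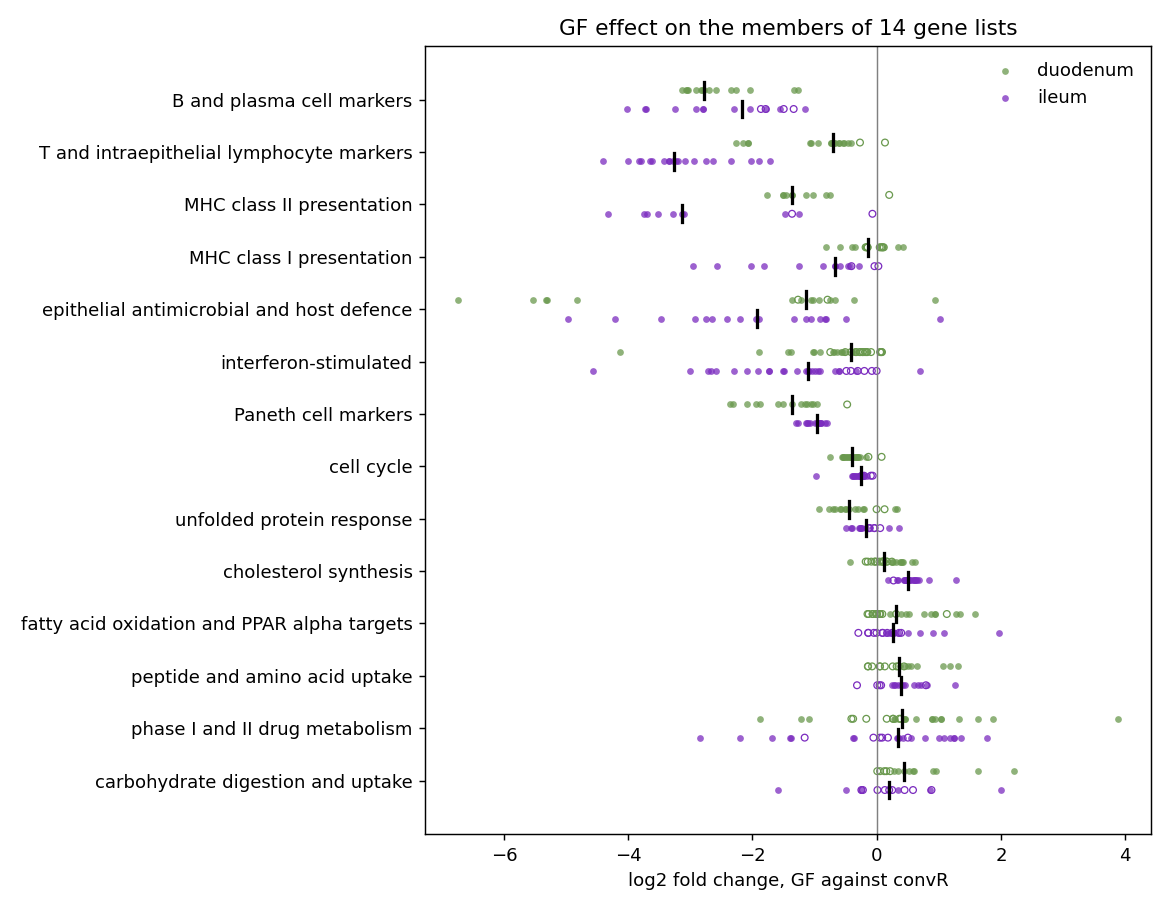
Log2 fold change of GF over convR for each measured member of 14 gene lists (x axis) by list (y axis), green for duodenum and purple for ileum. Filled points passed the threshold, open points did not, and black ticks are list medians, such as -2.78 for B and plasma cell markers in duodenum and -3.26 for T-cell markers in ileum.

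The second comparison asks the same of the ileum, with 12 convR and 11 GF libraries. T-cell and intraepithelial lymphocyte markers fell in 20 of 20 cases, with a median log2 fold change of -3.26 (camera adjusted p = 6.49e-37, 0.012 with an estimated correlation). Cd7, a surface protein of T and innate lymphoid cells, fell from 9.213 ± 3.7 to 0.8979 ± 0.207 CPM (SD, n = 12 and 11), a log2 fold change of -3.35 ± 0.205 (SE). Cd160, a receptor of intraepithelial lymphocytes, fell by 2.34, and Cd6, a T-cell receptor partner, fell by 4.41. MHC class II genes fell in 9 of 11 cases and 2 did not pass (median -3.13, camera adjusted p = 6.49e-37, 6.46e-04 with an estimated correlation). Cd74 fell 13-fold from 1406 ± 239 to 109.4 ± 27.9 CPM, a log2 fold change of -3.70 ± 0.152 (SE, edgeR adjusted p = 1.22e-12). H2-DMb1, which loads peptides onto class II molecules, fell by 4.32 from 65.37 ± 11.3 to 3.264 ± 0.808 CPM. MHC class I genes fell in 12 of 15 cases (median -0.67, camera adjusted p = 2.26e-09, adjusted p = 0.244 with an estimated correlation), with Psmb8, an immunoproteasome subunit, down by 2.58. Genes of the H2 family share sequence, so the division of reads among them is uncertain.

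Further immune groups fell in GF ileum. B and plasma cell markers fell in 12 of 16 cases (14 adjusted over the list alone, median -2.17, camera adjusted p = 3.25e-15, adjusted p = 0.0625 with an estimated correlation). Jchain fell from 795 ± 202 to 60.66 ± 18.8 CPM (SD, n = 12 and 11), a log2 fold change of -3.73 ± 0.183 (SE, adjusted p = 4.66e-11), and Igha fell by 4.02. Lymph node and follicle markers averaged 7.25 ± 4.38 CPM in convR and 3.84 ± 1.64 CPM in GF. Interferon-response genes fell in 25 of 32 cases and rose in 1 (26 adjusted over the list alone, median -1.10, camera adjusted p = 3.25e-15, adjusted p = 0.194 with an estimated correlation), with Gbp7, a GTPase against intracellular pathogens, at -1.51. Cytokine genes fell in 6 of 11 cases and rose in 2 (9 adjusted over the list alone, median -0.59, camera adjusted p = 0.0204, adjusted p = 0.194 with an estimated correlation), with Ccl28, which draws IgA cells, at -0.95. Macrophage and dendritic cell markers fell in 13 of 15 cases and rose in 1 (14 adjusted over the list alone, median -0.85, camera adjusted p = 3.88e-10, adjusted p = 0.0731 with an estimated correlation), with Csf1r, a growth factor receptor of macrophages, at -1.27. Adjusted over the list alone, 20 T-cell, 10 MHC class II and 12 MHC class I genes passed.

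Antimicrobial genes fell in 17 of 18 cases and rose in 1 (18 adjusted over the list alone, median -1.92, camera adjusted p = 3.64e-21, 0.00396 with an estimated correlation). Pigr (ENSMUSG00000026417, chr1:130826684-130852249), which carries IgA across the epithelium, fell from 2405 ± 355 to 647.7 ± 65.1 CPM, a log2 fold change of -1.90 ± 0.079 (SE, adjusted p = 4.59e-13). Dmbt1, a mucosal scavenger protein, fell by 2.20. Saa1, an acute-phase protein with a near-identical neighbour and hence an uncertain count, fell by 4.98. The largest fall that kept its sign was that of Ceacam10 (ENSMUSG00000054169, chr7:24777206-24784657), an adhesion molecule, from 18.88 ± 2.78 to 0.2048 ± 0.0913 CPM, -6.48 ± 0.146 log2 (SE, adjusted p = 1.46e-17). Slc6a14, an amino-acid transporter, fell by 5.42 and Ubd fell by 4.56. Paneth cell markers fell in 15 of 15 cases (15 adjusted over the list alone, median -0.95, camera adjusted p = 9.93e-10, adjusted p = 0.280 with an estimated correlation). Defa22, an alpha-defensin whose copies cannot be separated with certainty, fell from 1844 ± 323 to 874.3 ± 218 CPM. Cell-cycle genes fell in 21 of 25 cases (23 adjusted over the list alone, median -0.25, camera adjusted p = 8.03e-05, adjusted p = 0.641 with an estimated correlation), with Ccnd1, a cyclin of the start of the cycle, at -0.99.

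Cholesterol synthesis rose in GF ileum. Of 25 genes 24 rose and 0 fell (24 adjusted over the list alone, median 0.51, camera adjusted p = 1.53e-09, adjusted p = 0.316 with an estimated correlation). Fatty-acid oxidation genes rose in 10 of 22 cases (11 adjusted over the list alone, median 0.25, camera adjusted p = 6.93e-05, adjusted p = 0.194 with an estimated correlation). Among them Angptl4, an inhibitor of lipoprotein lipase, rose from 23.4 ± 12.3 to 85.28 ± 35.5 CPM (SD, n = 12 and 11), a log2 fold change of 1.98. Peptide and amino-acid uptake genes rose in 12 of 17 cases (13 adjusted over the list alone, median 0.39, camera adjusted p = 1.79e-04, adjusted p = 0.212 with an estimated correlation), with Slc6a19, the carrier of neutral amino acids, at 0.71. Drug-metabolism genes rose in 13 of 26 cases and fell in 7 (22 adjusted over the list alone, median 0.34, camera adjusted p = 0.0201, adjusted p = 0.641 with an estimated correlation), with Gsta1, a glutathione transferase, at 1.24 and Cyp3a25 at -1.69. Slc28a1, a nucleoside carrier, rose from 6.689 ± 4.76 to 44.99 ± 26.8 CPM, 2.85 ± 0.515 log2 (SE, adjusted p = 2.87e-04).

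Wall and stroma markers of the ileum moved too. Smooth muscle markers rose in 11 of 12 cases (11 adjusted over the list alone, median 0.33, camera adjusted p = 1.09e-04, adjusted p = 0.436 with an estimated correlation), from a mean of 170.7 ± 20.4 CPM in convR to 220.5 ± 20.3 CPM in GF. Actg2, the smooth muscle actin, rose from 114.1 ± 24.5 to 218.7 ± 23.6 CPM. Endothelial and fibroblast markers fell in 14 of 14 cases (14 adjusted over the list alone, median -0.39, camera adjusted p = 2.55e-05, adjusted p = 0.194 with an estimated correlation), with Col3a1, a collagen of loose tissue, at -0.43. Goblet cell markers fell in 6 of 15 cases and rose in 3, enteroendocrine markers fell in 6 of 17 and rose in 2, and stem cell markers split into 4 rises and 4 falls of 13, and none of these lists passed camera. Carbohydrate genes split into 3 rises and 3 falls of 15, fat-absorption genes into 4 and 4 of 23, and these lists did not pass either. Adipocyte markers fell in 6 of 11 cases (7 adjusted over the list alone, median -1.23, camera adjusted p = 0.0512). The mean level of clock genes rose in 8 of 19 cases and fell in 3 without a passing list (camera adjusted p = 0.213).

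Over all genes of the ileum, 7587 of 18082 passed with edgeR, 3535 higher and 4052 lower in GF. Of these 1093 differed by at least 1 log2, 161 upward and 932 downward. Scaled by library size only, 2316 were higher and 4866 lower.

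**Figure D2:**
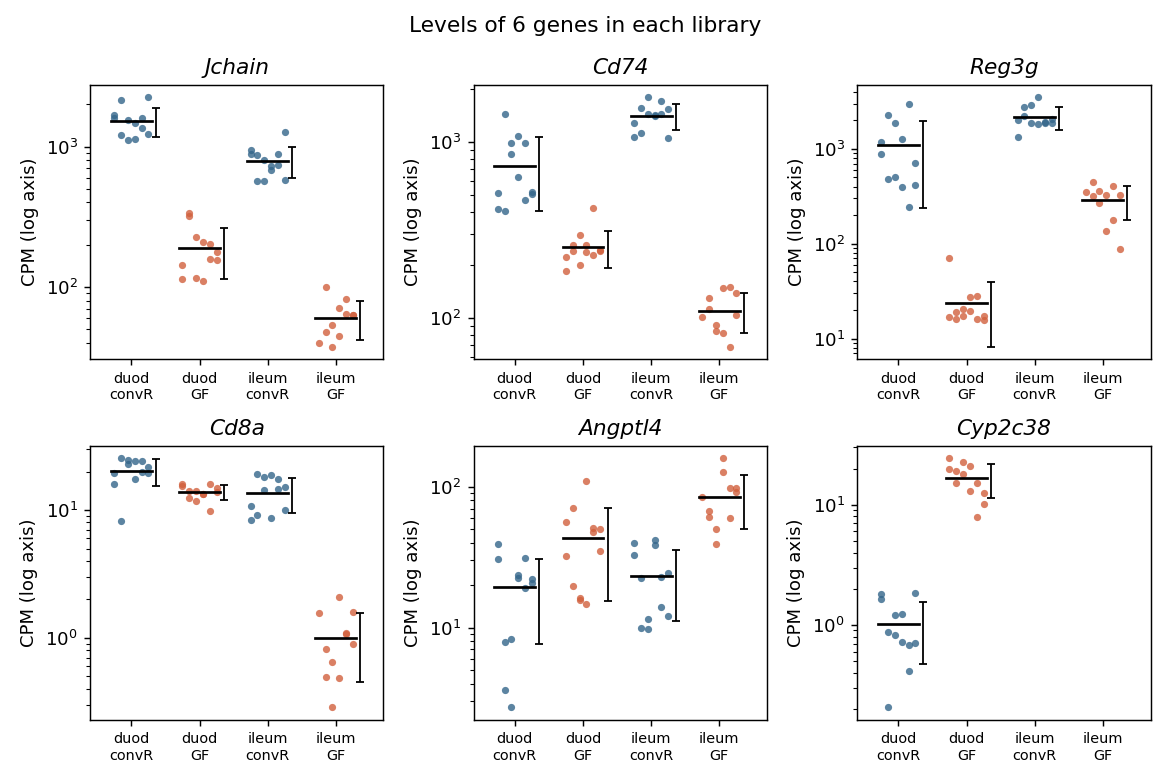
Level of 6 genes in each library (y axis, CPM, log scale) by tissue and status (x axis), with points for libraries, a line for the mean and a bar for the SD. Jchain falls from 1528 to 189.7 CPM in duodenum and from 795 to 60.66 CPM in ileum, and Cyp2c38, too low for testing in ileum, is drawn for duodenum only.

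The third comparison asks where the GF effect differs between the tissues, by the interaction of tissue and status. T-cell and intraepithelial lymphocyte markers fell further in ileum than in duodenum in 18 of 20 cases (19 adjusted over the list alone), with a median difference in log2 fold change of -2.39 (camera adjusted p = 1.09e-56, 4.13e-04 with an estimated correlation). Cd8a (ENSMUSG00000053977, chr6:71373427-71379173), the co-receptor of cytotoxic T cells, went from 20.74 ± 4.89 to 14.13 ± 1.88 CPM in duodenum (SD, n = 12 and 12) and from 13.3 ± 3.99 to 0.9769 ± 0.537 CPM in ileum (n = 12 and 11), a difference of -3.23 log2. Zap70, a kinase of the T-cell receptor, differed by -2.41 and Cd7 by -2.89. MHC class II genes fell further in ileum in 7 of 11 cases (7 adjusted over the list alone, median -1.98, camera adjusted p = 1.12e-18, 0.0125 with an estimated correlation). Pigr had the smallest p, with 5142 ± 841 CPM in convR and 4009 ± 708 CPM in GF duodenum against 2337 ± 344 and 632.2 ± 64.4 CPM in ileum. These levels are scaled over all 47 libraries. Its difference was -1.53 ± 0.116 log2 (SE, edgeR adjusted p = 1.9e-11). Ifnar2, a receptor of type I interferon, rose from 21.37 ± 2.77 to 37.19 ± 6.96 CPM in GF duodenum and fell from 10.89 ± 0.746 to 7.843 ± 0.804 CPM in GF ileum, a difference of -1.27 log2. Atg16l2, a relative of an autophagy protein, fell from 4.669 ± 0.617 to 3.549 ± 0.648 CPM in duodenum and rose from 6.969 ± 1.66 to 19.35 ± 4.7 CPM in ileum, a difference of 1.87 log2.

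Among the lists whose GF effect differed between tissues, MHC class I genes fell further in ileum in 12 of 15 cases (median -0.52, adjusted p = 0.120 with an estimated correlation) and interferon-response genes in 13 of 32 (median -0.54, adjusted p = 0.414 with an estimated correlation). Cholesterol-synthesis genes rose more in ileum in 9 of 25 cases (13 adjusted over the list alone, median 0.37, adjusted p = 0.414 with an estimated correlation). Plasma cell markers did not differ between tissues as a list, with 1 of 16 past the threshold, a median of -0.15 and a mean of 0.12. Over all genes 2331 of 19000 passed, 870 higher and 1461 lower in ileum, and 420 differed by at least 1 log2 (88 upward, 332 downward). Scaled by library size only the split was 1214 to 968.

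The GF effects of both tissues were related across genes. Over 17494 genes the log2 fold changes had a Pearson correlation of 0.786 and a Spearman correlation of 0.676. Genes are not independent replicates, so no p is given. Genes past the threshold in both tissues numbered 4910, of which 2053 were higher and 2662 lower in both, against 776.3 and 946.7 for independent calls. Residuals of convR libraries with equal numbers correlated between the tissues (0.207 to 0.588), so calls of both tissues are not independent and these expected counts are no firm reference. With disjoint replicate numbers the Pearson correlation was 0.686 or 0.693. Opposite directions were seen for 195 genes, Ifnar2 and Atg16l2 among them.

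The fourth comparison asks how ileum differs from duodenum within each status. In convR the distal intestine markers were higher in ileum in 14 of 14 cases (14 adjusted over the list alone), with a median log2 fold change of 4.01 (adjusted p = 9.30e-04 with an estimated correlation). Fabp6 (ENSMUSG00000020405, chr11:43596049-43601540), the bile-acid binding protein, rose from 0.939 ± 0.605 CPM in duodenum to 2789 ± 949 CPM in ileum (SD, n = 12 and 12), 11.52 ± 0.535 log2 (SE). Distal markers in duodenum averaged 0.846 ± 0.172 CPM in libraries numbered 1 and 0.425 ± 0.124 CPM in those numbered 2. Slc10a2, the bile-acid carrier, was higher by 8.52. Fgf15, a hormone released on bile-acid uptake, was higher by 11.08, a value that depends on a duodenum level near 0: over both statuses Fgf15 averaged 0.0414 CPM in duodenum libraries numbered 1 and 0 CPM in those numbered 2, and Fabp6 averaged 1.63 and 0.363 CPM. Tmprss15, which activates trypsin, stood at -11.22 ± 0.423 log2 (SE), from 366.7 ± 153 to 0.1485 ± 0.0969 CPM, and Tff2, a secreted peptide of stomach and Brunner glands, at -9.72, with a level of 592.6 ± 1970 CPM in duodenum that comes mostly from convR ZT14 replicate 1. Ctrc, a pancreatic protease, stood at -9.55, and pancreas markers in convR duodenum ranged from 1.65 CPM (ZT14 replicate 1) to 240 CPM (ZT22 replicate 2). Paneth cell markers were higher in ileum in 15 of 15 cases (median 1.98, adjusted p = 0.0622 with an estimated correlation) and goblet cell markers in 13 of 15 (median 0.95, 0.0020 with an estimated correlation). Drug-metabolism genes were lower in 21 of 26 cases (median -1.51, adjusted p = 0.230 with an estimated correlation), and mitochondrial genes in 19 of 19 (median -0.53, adjusted p = 0.378 with an estimated correlation). Antimicrobial genes gave a camera adjusted p = 0.0596, and 0.0108 with replicate numbers as a block.

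MHC class II genes differed between ileum and duodenum in opposite directions by status. In convR 7 of 11 were higher in ileum (median 0.81, camera adjusted p = 0.0285, adjusted p = 0.530 with an estimated correlation), and in GF 8 of 11 were lower (median -0.97, camera adjusted p = 0.0205, adjusted p = 0.530 with an estimated correlation). T-cell markers in GF were lower in ileum in 17 of 18 cases (17 adjusted over the list alone, median -2.99, 0.0340 with an estimated correlation). Cholesterol-synthesis genes in GF were higher in ileum in 23 of 25 cases with a median of 1.43, against 1.07 in convR. Over all genes 9015 of 18164 passed in convR, 4515 higher and 4500 lower in ileum, and 1664 differed by at least 1 log2. Scaled by library size only the convR split was 5092 to 3819. In GF 11918 of 17909 passed, 5940 higher and 5978 lower, and 2582 differed by at least 1 log2. Scaled by library size only the GF split was 7944 to 4601, with a shift of the median of 0.119.

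The fifth comparison asks which transcripts follow a 24 h rhythm in duodenum, and whether the rhythm differs by status. Of 19 clock genes 11 were rhythmic in convR and 12 in GF, 10 in both (18 and 17 adjusted over the list alone). Arntl (ENSMUSG00000055116, chr7:113207465-113314126), the activator of the core clock, had a peak-to-trough range of 2.48 ± 0.46 log2 in convR with a peak at ZT 22.8 ± 0.706 h (SE, n = 12), and of 3.50 ± 0.30 log2 in GF with a peak at ZT 21.9 ± 0.329 h. Tef, a clock output regulator, peaked at ZT 12.2 ± 0.70 h in convR and ZT 10.7 ± 0.17 h in GF. Bok, a relative of apoptosis regulators, and Aldh18a1, an enzyme of proline synthesis, were rhythmic in both groups. Over all genes 149 were rhythmic in convR, 246 in GF and 52 in both, against 2.04 for independent calls. Both calls come from the same fit with a shared dispersion per gene, so they are not independent and this expected count is no firm reference. Which status had more depends on the fit: fitted on that status alone the counts were 5 in convR and 432 in GF, with DESeq2 626 and 574, and with time as a factor 213 and 143. Without ZT6 the counts were 297 and 652. A difference of rhythm by status passed in 0 genes with edgeR, 0 with DESeq2 and 0 with limma-voom, and 739 had an unadjusted p <0.05. Adjusted over the list alone, 1 of 23 fatty-acid oxidation genes differed, Ppara. Ppara peaked at ZT 14.4 in convR and ZT 10.8 in GF. The same adjustment passed 3 of 11 cytokine genes and 3 of 3 stomach and Brunner gland markers. It also passed 1 of 25 cholesterol-synthesis and 1 of 15 fatty-acid synthesis genes, but 0 of 19 clock genes. Such calls are not corrected for the number of lists. The stomach markers averaged 1469 CPM in convR ZT14 replicate 1 and 463.2 CPM in GF ZT22 replicate 2. The convR count was 43 without the 7 libraries that stood apart, a fit that lost convR ZT14 and GF ZT22 altogether. Single libraries weighed on the convR count as well. Leaving out 1 library gave 22 (convR ZT10 replicate 1), 92 (convR ZT10 replicate 2), 29 (convR ZT14 replicate 1), 93 (convR ZT14 replicate 2), 86 (convR ZT18 replicate 1), 69 (convR ZT18 replicate 2), 95 (GF ZT10 replicate 1), 99 (GF ZT18 replicate 2) and 232 (GF ZT6 replicate 1). The GF count gave 383 (without convR ZT6 replicate 1), 88 and 89 (without GF ZT10 replicates 1 and 2), 152 (without GF ZT2 replicate 2), 130 (without GF ZT22 replicate 2) and 375 (without GF ZT6 replicate 1).

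In ileum 10 of 19 clock genes were rhythmic in convR, 14 in GF and 9 in both (16 and 18 adjusted over the list alone). Arntl peaked at ZT 0.958 ± 0.568 h in convR (SE, n = 12) and ZT 23.45 ± 0.167 h in GF (n = 11), with ranges of 2.22 ± 0.33 and 2.995 ± 0.13 log2. Dbp, a clock output regulator, peaked at ZT 12.4 ± 0.693 h in convR and ZT 10.2 ± 0.163 h in GF. Fatty-acid oxidation genes were rhythmic in 1 of 22 cases in convR and 5 in GF (2 and 8 adjusted over the list alone). Endothelial and fibroblast markers were rhythmic in 3 of 14 cases in convR and 0 in GF (9 and 1 adjusted over the list alone). Tested for a rhythm difference by status, 0 genes of either list passed, also when adjusted over the list alone. The unequal counts are thus no evidence of a difference. Over all genes 136 were rhythmic in convR, 170 in GF and 55 in both, against 1.28 for independent calls. As in duodenum, both calls share a fit and its dispersion, so this expected count is no firm reference. Fitted on that status alone the counts were 22 in convR and 226 in GF, with DESeq2 379 and 367, with time as a factor 141 and 55, and without ZT6 58 and 110. A difference by status passed in 0 genes with edgeR, 0 with DESeq2 and 0 with limma-voom, and 608 had an unadjusted p <0.05. Adjusted over the list alone, 7 of 19 clock genes differed by status, among them Arntl, Cry1, Nr1d2, Dbp, Tef and Nfil3. The same adjustment passed 1 of 11 cytokine genes and 2 of 4 mast cell markers. As in duodenum, such calls are not corrected for the number of lists. Leaving out 1 library changed the convR count to 83 (convR ZT10 replicate 1), 60 (convR ZT10 replicate 2), 24 (convR ZT14 replicate 1), 54 (convR ZT14 replicate 2), 89 (convR ZT18 replicate 2), 81 (convR ZT2 replicate 2) and 258 (convR ZT22 replicate 1). It changed the GF count to 92 (GF ZT10 replicate 2), 110 (GF ZT2 replicate 2), 112 (GF ZT22 replicate 1) and 110 (GF ZT6 replicate 1).

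The clock genes rhythmic in both groups were earlier in GF on average, but the shift did not pass in either tissue. In duodenum the circular mean over 10 genes was -1.13 h (SD over genes 0.967 h), with 9 earlier in GF, and an exact permutation p = 0.307. With the 10 clock genes named before the data were examined it was -0.64 h (exact permutation p = 0.396), and without convR ZT6 replicate 2 it was -0.55 h (exact permutation p = 0.618). In ileum it was -1.62 h (SD 0.408 h), with 9 of 9 earlier, and an exact permutation p = 0.0938. Per3, a repressor of the clock, shifted by -1.01 ± 0.756 h in duodenum (SE) and by -1.29 ± 0.562 h in ileum. The ileum shift passed with the same 10 named clock genes (-1.74 h, exact permutation p = 0.0053), without ZT22 (-1.71 h, exact permutation p = 0.0463) and without convR ZT18 replicate 1 (-1.95 h, exact permutation p = 0.0360). Read by their clock genes against the curves of the other status, the convR ZT6 libraries lay -2.95 h from their label on average in duodenum and -3.45 h in ileum. Averages as far off were -3.55 h for convR ZT14 in ileum and 4.8 h for GF ZT6 in duodenum. Other libraries 3 h or more from their label were, in duodenum, GF ZT6 replicate 1 (8.7 h), convR ZT22 replicate 2 (4.2 h), GF ZT14 replicate 1 (-3.3 h) and GF ZT18 replicate 1 (3 h), and in ileum convR ZT22 replicate 1 (5.6 h) and convR ZT14 replicate 2 (-4.8 h). Without ZT6 the shifts were -0.085 h in duodenum and -0.70 h in ileum.

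**Figure D3:**
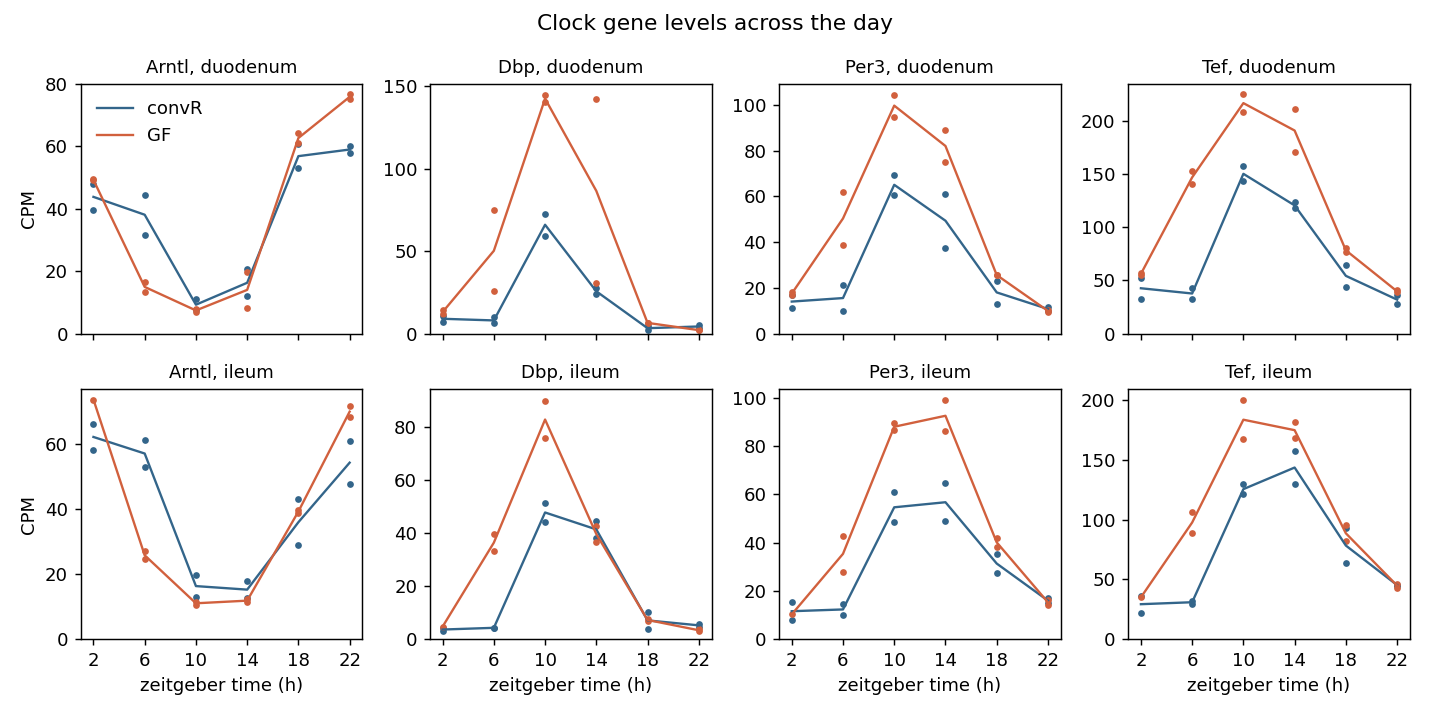
Level of Arntl, Dbp, Per3 and Tef (y axis, CPM) by zeitgeber time in hours (x axis) in duodenum and ileum, with points for libraries and lines for the means of GF and convR. Arntl in ileum peaks at ZT 0.958 h in convR and ZT 23.45 h in GF by the fitted cosine.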

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

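The tests of scaling and of a whole-day shift for the clock, of a swap in GF, of pancreas transcripts over 10 CPM, of status for pancreas and stomach markers, and of reads carried over or neighbouring tissue were chosen only after the result was seen.

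The GF effect differed between ileum and duodenum for 18 gene lists and for many named genes, each a difference between groups, but only 2 of these lists, T-cell markers and MHC class II genes, kept their call with an estimated correlation. Values here are medians, or single differences, of the ileum minus duodenum log2 fold change. Lower in ileum were T-cell markers (-2.39), MHC class II (-1.98) and class I genes (-0.52), interferon-response genes (-0.54), macrophage markers (-0.26), adipocyte markers (-0.98), tuft cell markers (-0.43), enteroendocrine markers (-0.40), carbohydrate genes (-0.30), endothelial and fibroblast markers (-0.21) and drug-metabolism genes (-0.091). Higher in ileum were Paneth cell markers (0.39), cholesterol synthesis (0.37), smooth muscle markers (0.31), stem cell markers (0.28), fatty-acid synthesis (0.25), unfolded protein response (0.23) and cell cycle (0.12).

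Among lymphocyte and antigen-presentation genes the differences were -3.23 for Cd8a, -2.89 for Cd7, -2.41 for Zap70, -2.33 for Cd6, -1.87 for Lck, -1.72 for Cd160, -2.55 for H2-DMb1, -2.19 for Cd74, -2.17 for Psmb8, -0.96 for Igha, -0.69 for Csf1r, -1.15 for Gbp7 and -1.27 for Ifnar2. Among epithelial defence genes they were -1.53 for Pigr, -1.44 for Dmbt1, -3.70 for Saa1, -2.12 for Ceacam10, 2.62 for Reg3g, 2.91 for Duox2, 3.29 for Nos2, 0.94 for Mmp7, 2.24 for Mptx2 and 1.23 for Defa22. Among the other named genes they were 5.44 for Slc5a8, 1.85 for Slc28a1, 1.87 for Atg16l2, -1.50 for Sst, -1.52 for Cyp3a25, -3.30 for Cyp2c29, -1.61 for Cd36, 0.98 for Tfrc, -2.69 for Cybrd1, -0.81 for Epas1, -0.74 for Ahrr, 0.60 for Actg2, -0.30 for Col3a1, 0.41 for Hsp90b1 and 0.53 for Lgr5.

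In ileum several clock genes differed in rhythm by status when adjusted over the list alone, with a peak time GF minus convR of -1.504 h for Arntl, -3.15 h for Cry1, -1.91 h for Nr1d2, -2.21 h for Dbp, -1.93 h for Tef and -1.31 h for Nfil3.

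The clock genes peaked earlier in GF on average, a shift that did not pass in the main test (exact permutation p = 0.307 in duodenum and 0.0938 in ileum). With the 10 clock genes named before the data were examined it passed in ileum (exact permutation p = 0.0053) and not in duodenum (exact permutation p = 0.396). It also passed in ileum without ZT22 (exact permutation p = 0.0463). The convR ZT6 libraries read -3.45 h from their label in ileum and -2.95 h in duodenum, with convR ZT14 in ileum at -3.55 h. The choice between TMM and library size did not make the shift, which was -1.10 h in duodenum and -1.65 h in ileum by library size only. An error shared by both scalings was not tested. In GF ileum 0 libraries of other times lay 3 h or more from their label, and those of ZT6 lay 0.9 to 2.1 h from it. These readings argue against a swap of ZT6 with another time there. As gaps at other times reached 5.6 h in ileum, such a swap is not excluded. It stays open in convR of both tissues and in GF duodenum, where GF ZT6 replicate 1 read 14.7 h and GF ZT14 replicate 1 read 10.7 h: 0 libraries read within 1.5 h of ZT6, the sign set in advance for convR, but gaps at other times reached 5.6 h in ileum and 4.2 h in duodenum, which makes that bound too narrow, and the nearest GF duodenum library, at 4.7 h from ZT6, passes the gap of its own tissue only. A shift of the whole day cannot be told apart from an effect of ZT6 alone, as the shift without ZT6 was -0.085 h in duodenum and -0.70 h in ileum.

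Pancreas transcripts, above the other samples in 8 duodenum libraries, could come from pancreas tissue left on the sample. The lowest correlation across 17 acinar genes was 0.95 among the 4 libraries over 100 CPM and 0.917 among all 8, which is consistent with a single kind of source. An effect of germ-free status cannot be told apart from chance for pancreas markers (permutation p = 0.316) or for stomach and Brunner gland markers (permutation p = 0.811).

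Distal intestine markers in duodenum, and liver markers in both tissues, were higher in libraries numbered 1 than in those numbered 2, which could reflect reads carried over between libraries, while pancreas markers in convR were higher in number 2 at 5 of 6 times in duodenum and 6 of 6 in ileum. In duodenum distal intestine markers averaged 0.846 ± 0.172 CPM in number 1 and 0.425 ± 0.124 CPM in number 2, a mean log2 difference of 0.94 over 12 pairs (exact p = 4.88e-04). The prediction for carry-over, a rise of both distal and liver markers, was met but was written after the rise was seen. The test of neighbouring fat or vessels asked only for this same rise of distal markers, so it cannot decide on that source. Liver markers rose too, by 1.27 log2 in duodenum and 1.45 log2 in ileum, and for them neighbouring fat cannot be told apart, since adipocyte markers differed by 0.216 log2 (exact p = 0.162) and 0.473 log2 (exact p = 0.0596). In ileum proximal markers were lower in number 1 (-1.49 log2, exact p = 0.0391), and carry-over or neighbouring tissue cannot be told apart there, as the carry-over needed (0.347 CPM) is far below the spread of these markers (SD 32.3 CPM). The excess in duodenum was 0.0465% of the ileum level for Fabp6 and 0.131% for Fgf15, most of the number 1 level of these genes, but for Slc10a2 (0.964 against 0.799 CPM) and Plb1 (0.746 against 0.537 CPM) most of that level was present in number 2 as well.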

How the results depend on the processing

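The tests without libraries that stood apart, and those of rhythm counts without ZT6, were chosen only after the result was seen. Of values for named genes, 5104 in duodenum kept their call and 92 lost it, 4798 and 150 in ileum, 4329 and 14 between tissues in convR, 4004 and 39 in GF, and 462 and 0 for the tissue difference. Rhythm calls were less stable: 408 kept and 130 lost in convR duodenum, 460 and 77 in GF duodenum, 387 and 65 in convR ileum, and 511 and 44 in GF ileum. Lists kept their call in 336 cases and lost it in 112. At 1 log2 or more the counts were 838 in duodenum, 1093 in ileum, and 1664 (convR) and 2582 (GF) between tissues. With an estimated correlation 0 lists passed in duodenum, 3 in ileum, 2 and 5 between tissues in convR and GF, and 2 for the tissue difference, and fry passed 28 in ileum. The correlation of GF effects was 0.805 over genes past 5%, 0.828 over 5 CPM and 0.765 without libraries that stood apart.

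In duodenum convR rhythm gave 626 genes (DESeq2), 5 (that status alone), 66 (log2 range of 1), 43 (without libraries that stood apart), 297 (without ZT6) and up to 232 without 1 library. GF rhythm gave 132 (12 h term), 574 (DESeq2), 432 (status alone), 120 (range), 143 (time as factor), 652 (without ZT6) and up to 383. In ileum convR rhythm gave 379 (DESeq2), 22 (status alone), 52 (range), 58 (without ZT6) and up to 258, and GF rhythm 97 (12 h term), 367 (DESeq2), 71 (range), 55 (time as factor), 110 (without ZT6) and up to 188. Without replicate 1 or 2, with fewer samples, the counts were 0 and 3 in convR duodenum and 1 and 1 in GF duodenum. In ileum they were 1 and 0 in convR and 12 and 1 in GF. The cause was not tested.

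The clock shift of the duodenum was -0.64 h with 10 named genes and -0.55 h without convR ZT6 replicate 2. That of the ileum was -1.74 h with 10 named genes, -1.71 h without ZT22, and ran from -1.95 to -1.30 h without 1 library. With 1 library left out, counts reached 8673 in duodenum, 7724 in ileum and 2516 for the tissue difference. Without replicate 1 or 2 they were 6415 and 4408, 6015 and 4156, and 1136 and 409, with fewer samples. Cxcl13 in ileum (-0.94, adjusted p = 0.0499) was -1.57 without replicate 2 and reversed to 0.11 without replicate 1, and the cause was not tested.

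With replicate numbers as a block the counts were 8514, 7908, 2847 for the tissue difference, and 9932 and 11658 between tissues. The correlation of residuals of equal numbers across status reached r = 0.255 in duodenum and 0.407 in ileum. The clock list in duodenum lost its call (0.0539). Disjoint replicate blocks gave effect correlations of 0.686 and 0.693.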

Other observations

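In this part the predictions for the splits of samples were written before their results, and the tests of amplitude were chosen only after the result was seen.

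Genes of oxidative defence went both ways within their list in each tissue. Of 16 glutathione and antioxidant genes in duodenum 6 rose and 6 fell in GF (12 adjusted over the list alone, median 0.04, mean -0.06), with Cat, which breaks down hydrogen peroxide, at 0.98 and Gpx2, a glutathione peroxidase of the gut, at -1.22. In ileum 6 rose and 7 fell (14 adjusted over the list alone, median 0.11, mean -0.02), and Gclc, the first enzyme of glutathione synthesis, rose from 75.11 ± 12.9 to 182.1 ± 39.8 CPM (SD, n = 12 and 11). The list passed camera in neither tissue. Iron genes rose in 3 of 9 cases in duodenum and fell in 0 (3 adjusted over the list alone, median 0.80, camera adjusted p = 0.0249, adjusted p = 0.531 with an estimated correlation), with Epas1, a hypoxia factor that drives iron uptake, at 0.86. In ileum 2 rose and 3 fell (5 adjusted over the list alone), with Tfrc, the transferrin receptor, at 1.17 and Cybrd1, an iron reductase, at -0.77. Targets of the aryl hydrocarbon receptor passed in neither tissue as a list. The repressor Ahrr fell by 0.89 in duodenum and fell by 1.64 in ileum, and in duodenum the list had a median of 0.10, a mean of -0.18 and a downward test direction. In ileum glucocorticoid-response genes rose in 6 of 11 cases and fell in 2 (camera adjusted p = 0.116), with Mt1, a metal-binding protein, at 1.27. Polyamine, arginine and citrulline genes rose in 5 of 15 cases and fell in 1, with Odc1, the first enzyme of polyamine synthesis, at 0.65. Genes of the unfolded protein response fell in 9 of 17 cases and rose in 2 in ileum, without a passing list (camera adjusted p = 0.147), and fatty-acid synthesis genes rose in 8 of 15 cases (camera adjusted p = 0.0577).

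Of genes rhythmic in both groups, 33 of 52 in duodenum had a larger peak-to-trough range in GF (median difference 0.09 log2). There 40 peaked earlier, with a circular mean shift of -0.751 h. In ileum 45 of 55 had a larger peak-to-trough range (median difference 0.15 log2) and 46 peaked earlier, with a shift of -1.17 h. For the clock genes rhythmic in both groups the mean peak-to-trough difference was 0.96 log2 in duodenum (exact permutation p = 0.0265) and 0.55 log2 in ileum (exact permutation p = 0.0691), a test chosen after the data were seen. Gene by gene, a rhythm difference by status passed over the list alone in 0 of 19 clock genes in duodenum and 7 of 19 in ileum. The range was not tested without ZT6, where convR libraries read -2.95 h (duodenum) and -3.45 h (ileum) from their label on average.

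That chance might give the counts was tested with splits of the same libraries, Jchain, Cd74 and all other tested genes included. For GF against convR, 1 of the 100 splits in duodenum reached the real count of 8328 genes, the real one itself, and the highest other gave 3136. That other kept 20 of 24 libraries as labelled. In ileum 1 of the 100 splits reached the real 7587 and the highest other gave 188. For the tissue difference of the GF effect 1 of the 50 splits reached the real 2331 and the highest other gave 0. Those splits swapped status within each tissue and time, without keeping the pairs of replicate numbers across tissues. Between ileum and duodenum in convR 1 of the 100 splits reached the real 9015 and the highest other gave 2840. There residuals of equal replicate numbers correlated between tissues, though whether they mark the same mouse is not known. Taken as pairs, all 12 were parted by 10 other splits as by the real one, with a highest count of 0. The remaining 89 parted fewer pairs. In GF 1 of the 100 splits reached the real 11918, and the highest other gave 8995 with 20 of 23 libraries as labelled. None of the other splits drawn thus reached the counts of GF against convR or between tissues, which bounds chance no lower than 1 in 100. The splits treat libraries as separate units, which the replicate numbers do not show. For the tissue difference the bound is 1 in 50, and only against splits that ignore a possible pairing.

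For rhythms in duodenum 1 of the 60 splits reached the real count of 149 in convR, with a highest other of 44, and 1 of the 60 reached 246 in GF, with a highest other of 96. In ileum 1 of the 60 splits reached 136 in convR, with a highest other of 1, and 1 of the 60 reached 170 in GF, with a highest other of 4. For the difference of rhythm by status the real count was 0 in both tissues, which 60 of the 60 splits reach by construction, so that test is void and says nothing about chance. The highest other count was 2 in ileum. In duodenum 1 split called 4720 genes and the next highest 4, and the cause was not tested.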
